A study of Bos taurus with 6 samples.

How the data were processed

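Poly(A) RNA of bovine fetal forebrain, liver and rumen was sequenced with 2 libraries per tissue, all labelled male, and made with the NEBNext Ultra kit, per the labels' protocols. The fetuses were those of Holstein cows at a slaughterhouse, at 90 days by crown-rump length, per the labels' protocols. Reads were aligned with HISAT2 2.0.5, counted with featureCounts 1.5.0-p3 and analysed with edgeR 3.18.1, per the submitters' processing notes. The genome build, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited values used were the authors' raw counts per gene symbol, whole numbers with no scaling, in 1 column per library, and each of the 6 columns matched its label by name (0 unmatched). The table held 14179 symbols, of which 1359 had no counts in any library. A RefSeq gene table was used only to check names and to order neighbouring genes. It listed 13929 of the symbols, and 167 more as synonyms. Of all symbols in the count table, matched or not, 221 were provisional LOC names. In addition, 2 pairs of symbols differed only in letter case and were kept apart. Symbols absent from the table say nothing about expression.

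Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for camera and voom and DESeq2 1.42.0 for alternatives. TMM scaling factors were 1.20 and 1.13 in forebrain, 0.812 and 0.840 in liver, and 1.01 and 1.07 in rumen. CPM was computed on the total times this factor, the effective library size. The filter filterByExpr kept 11478 genes. A quasi-likelihood model with 1 mean per tissue, no block and 3 residual degrees of freedom gave 3 comparisons, rumen minus forebrain, rumen minus liver and liver minus forebrain, with Benjamini-Hochberg adjustment over all tested genes in each and a threshold of 0.05. Log2 fold changes are edgeR's, with a prior count, and printed folds are the same values on the linear scale, so they can differ slightly from the ratio of the printed mean CPM. A gene was tissue-enriched where it passed in both comparisons with a log2 fold change of at least 2. At the depths reached, 3 counts in 1 library corresponded to 0.244 and 0.217 CPM in forebrain, 0.223 and 0.193 in liver and 0.230 and 0.234 in rumen. Where a tissue had no counts, the fold is a bound: the pooled level of the other tissue (counts of both libraries over both effective library sizes, which can differ from the printed mean CPM) over the level of 3 counts in both libraries of the empty tissue, and none is given where a tissue had 1 to 3 counts. The scripts were tested on simulated data. Among 11297 genes drawn with the spread of these libraries, the test found 2% of 2-fold, 54% of 4-fold, 72% of 8-fold and 84% of 16-fold changes in rumen against forebrain, with 8 false among 114 calls. Against liver it found 0%, 50%, 76% and 90%, with 13 false among 121 calls, so changes of 2-fold were mostly missed there. The share of false calls lay above the threshold of 0.05 in both comparisons of these simulated data. Only 50 genes were changed at each fold in these simulated data. In the real comparisons 41.8% of tested genes passed against forebrain and 43.0% against liver. The adjustment is stricter where few genes change, so the simulated shares do not carry over to the real data.

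Gene lists, 40 in number, were written from general knowledge before the data were examined. Those of the nervous system were forebrain patterning factors, neurons, radial glia and astrocytes, oligodendrocyte lineage and the enteric nervous system. Those of liver and blood were hepatocyte secreted proteins, hepatocyte transcription factors, urea cycle, gluconeogenesis and amino acid breakdown, erythroid cells, megakaryocytes and platelets, haematopoietic progenitors, macrophages and Kupffer cells, lymphocytes, granulocytes and endothelium. Those of the rumen wall and its surroundings were stratified squamous epithelium, general epithelium, foregut and stomach mesenchyme factors, smooth muscle, fibroblasts and extracellular matrix, pericytes and stellate cells, mesothelium, skeletal muscle, pancreas and spleen neighbours, glandular stomach and intestine, respiratory, rumen ketone body formation, and rumen fatty acid, ion and urea transport. The others were HOX clusters, hedgehog, BMP and WNT signalling, retinoic acid and FGF signalling, DNA methylation enzymes, Polycomb and Trithorax, imprinted genes, germline genes, proliferation, immediate early and stress response, and hypoxia and glycolysis. Lists of mitochondrially encoded proteins and of genes to check sex had no tested member and were not analysed here. The calls of each list were counted with the adjustment over all genes and again with an adjustment over the list alone. Lists of at least 3 tested members, 37 in all, were tested with camera, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the lists. Enriched genes were set against the lists with Fisher's exact test, and against simulated unchanged tissues that share libraries.

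The tests, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. Genes are named where they were among the 10 enriched genes of a tissue with the largest smaller fold change and a mean of at least 20 CPM, among the 4 members of a list past the test with the largest fold change or its 3 most abundant members, or among the 5 genes with the largest share of a tissue's counts. Provisional LOC names and ENSBTAG identifiers were passed over in the ranking of enriched genes. The members behind a count of 5 or fewer are named too, except a few genes that are not reported here. Those outside the rule in the comparisons of tissues, chosen after their values were seen, were ALDH1L1, BDH2, CA2, CBX8, CSPG4, DPY30, HHIP, HK1, HLX, HOXA9, KCNJ8, LORICRIN, LRAT, MEN1, MEST, NDN, NES, NKX2-2, NR2F1, PDGFRB, PFKP, RHCG, RING1, SLC16A3, SLC9A3 and STRA6. Genes named to describe the pairs of libraries, such as OTP and SOX14, did not follow the rule either. Alternatives were the DESeq2 size factors, upper quartile factors, TMM without genes over 0.5% of a library, no filter, a filter at a mean of 5 CPM in at least 1 tissue, the DESeq2 Wald test, limma-voom, edgeR's legacy dispersion, glmTreat against a 2-fold change (4-fold for enriched genes), only the 4 libraries of the tissues compared, the replicate number as a block, other minimum fold changes for enriched genes, and leaving out each library in turn. With a library left out the filter was run again, so the tested members of a list could change. With 2 libraries per tissue no test by regrouping samples was made. Chromatin marks and any data other than these RNA libraries were not used here. Floors cover counting error only, while SDs and SEs also hold the spread between libraries of a tissue. No difference between animals can be separated from one between preparations.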

Results

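Poly(A) RNA was sequenced from the forebrain, the liver and the rumen, the largest forestomach chamber of cattle, of male Holstein fetuses at 90 days of gestation. Each tissue had 2 libraries, called here Forebrain 1 and 2, Liver 1 and 2, and Rumen 1 and 2, and the 6 libraries shared 1 table of counts per gene. The fetuses came from a slaughterhouse and measured 13 to 16 cm from crown to rump. Per the labels, 2 of the fetuses were male and all 6 libraries were male, so the libraries came from at most 2 fetuses. Tissues thus shared fetuses, which the main fit, without a block, leaves out of account. The labels do not say which fetus gave which library, so the p-values measure only the spread between these samples, which may be technical. Total counts were 10271024 and 12295634 in Forebrain 1 and 2, 16550273 and 18528958 in Liver 1 and 2, and 12910828 and 11936981 in Rumen 1 and 2. Of the 14179 gene symbols in the table, between 11048 (Rumen 2) and 11748 (Forebrain 1) had at least 1 count in a library. Levels are given as CPM, counts scaled to the effective library size. A floor of 3 counts over both libraries of a tissue corresponded to 0.115 CPM in forebrain, 0.103 in liver and 0.116 in rumen. These floors cover counting error only, and a fold against a tissue without counts is the level pooled over both libraries of the other tissue against this floor. Where a count is given without a library, the filter was run again, so that the tested members of a list could differ. Such a fit also has fewer residual degrees of freedom. A member that no longer passed there need not have an unstable level.

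The 2 libraries of a tissue resembled each other more than those of other tissues, with a Pearson correlation of log2 CPM across genes of 0.983 in forebrain, 0.922 in liver and 0.971 in rumen. Between tissues the correlation lay from 0.448 to 0.702. Genes are not independent replicates, so these correlations only describe the libraries. Every pair differed by more than sampling noise, with a chi-square per degree of freedom of 18.3 in forebrain, 15.9 in rumen and 296 in liver, so no library was a copy of another. The liver pair stood apart. Over genes with a mean count of at least 1000, the log2 ratio of its 2 libraries had an SD of 0.945, against 0.249 in forebrain and 0.211 in rumen. In liver, AHSG, a plasma protein of the fetus also called fetuin-A, took 6.85 ± 1.67% of all counts (SD, n = 2), the fetal haemoglobin chain HBG 6.004 ± 4.04%, the protease inhibitor SERPINA1 4.501 ± 1.44%, albumin (ALB) 2.56 ± 1.11% and alpha-fetoprotein (AFP) 2.01 ± 0.306%. The leading genes of rumen were the translation factor EEF1A1 at 1.57 ± 0.0370%, the ribosomal protein gene RPLP1 at 1.32 ± 0.0854%, TPT1 at 1.30 ± 0.0167%, the growth factor IGF2 at 0.954 ± 0.0654% and the imprinted RNA H19 at 0.938 ± 0.0978% (SD, n = 2). Forebrain had no such dominant gene. EEF1A1 led there at 0.720 ± 0.0242%, followed by the actin ACTG1 at 0.663 ± 0.0148%, the stathmins STMN2 at 0.639 ± 0.0519% and STMN1 at 0.619 ± 0.0638%, and NNAT at 0.604 ± 0.0324% (SD, n = 2). Reads of EEF1A1, RPLP1, TPT1, ACTG1 and the haemoglobins can be shared with near-identical copies, so the levels of these genes are uncertain.

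Rumen and forebrain were compared first, under the question of which transcripts set the rumen apart from forebrain and liver, the only other tissues here. Rumen was rich in transcripts of stratified epithelium, smooth muscle and collagen matrix that were scarce in forebrain. KRT15, a keratin of basal cells in stratified epithelia, stood at 7067 ± 1125 CPM (SD, n = 2) in rumen and had no counts in forebrain, which puts its pooled level at least 61662-fold above the floor of forebrain. IVL, the cornified envelope protein involucrin, stood at 375 ± 65.2 CPM (SD, n = 2) in rumen, again with no counts in forebrain and at least 3272.9-fold higher. PERP, a protein of desmosomes, was 162-fold higher in rumen, at 964 ± 28.6 against 5.92 ± 0.0959 CPM (SD, n = 2; adjusted p = 9.43e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The mucosal keratin KRT4 reached 4201 ± 583 CPM in rumen and 0.180 ± 0.255 CPM in forebrain (SD, n = 2). Reads of keratin genes can be shared between family members, so their levels carry that uncertainty. Of the stratified squamous epithelium list, 15 of 19 tested members were higher and 2 lower (15 and 2 adjusted over the list alone). The lower members, named after their values were seen, were LORICRIN, a cornified envelope protein at 27.8 ± 3.82 CPM in forebrain and 0.195 ± 0.276 CPM in rumen, and the ammonium transporter RHCG, at 2.47 ± 0.424 CPM in forebrain and without counts in rumen (SD, n = 2). The number of lower members was 1 without either Forebrain library or either Rumen library. Among general epithelial genes, 12 of 15 tested members were higher and 0 lower (13 and 0 adjusted over the list alone). They included the adhesion molecule EPCAM, 20.5-fold higher in rumen at 188 ± 24.2 CPM, the keratin KRT19, 7.78-fold higher at 273 ± 45.6 CPM, and the tight junction gene CLDN4, at 48.6 ± 15.2 CPM in rumen and without counts in forebrain (SD, n = 2). By camera, a test of each list against all other genes, stratified squamous epithelium was higher at adjusted p = 4.21e-08 (adjusted p = 0.307 with an estimated correlation), and general epithelium at adjusted p = 4.77e-09 (adjusted p = 0.178 with an estimated correlation).

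Smooth muscle and matrix genes formed the other part of the rumen profile. Smooth muscle actin, ACTA2, stood at 1878 ± 143 CPM (SD, n = 2) in rumen and 27.5 ± 10.3 CPM in forebrain, a 68.1-fold difference (log2 fold change 6.09 ± 0.35 (SE); adjusted p = 8.70e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The myosin light chain kinase MYLK was 214-fold higher at 2655 ± 345 CPM, and the intermediate filament gene DES 708-fold higher at 575 ± 66.4 CPM (SD, n = 2). In the smooth muscle list, 15 of 17 tested members were higher and 0 lower (16 and 0 adjusted over the list alone). The fibrillar collagen COL3A1 was among the most abundant rumen transcripts of the lists, at 8576 ± 275 CPM against 44.6 ± 12.4 CPM in forebrain, 192-fold (SD, n = 2). The microfibril gene MFAP4 was 288-fold higher at 422 ± 52.3 CPM, and LOX, an enzyme that crosslinks collagen, stood at 20.8 ± 5.29 CPM without counts in forebrain (SD, n = 2). For fibroblasts and extracellular matrix, 16 of 17 tested members were higher and 0 lower (16 and 0 adjusted over the list alone). The camera call was adjusted p = 6.53e-12 (adjusted p = 0.178 with an estimated correlation) for smooth muscle, and adjusted p = 5.25e-14 (adjusted p = 0.293 with an estimated correlation) for extracellular matrix.

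Genes of regional identity also separated rumen from forebrain. In the HOX clusters, whose genes mark position along the body axis, 11 of 12 tested members were higher and 0 lower (11 and 0 adjusted over the list alone). HOXC4 stood at 62.3 ± 2.18 CPM, HOXA5 at 34.0 ± 2.88 CPM and HOXA3 at 16.0 ± 0.933 CPM in rumen (SD, n = 2), all 3 without counts in forebrain. Their list was higher in rumen by camera at adjusted p = 1.44e-08 (adjusted p = 0.148 with an estimated correlation). The homeobox gene PITX1 stood at 426 ± 2.78 CPM (SD, n = 2) in rumen and had no counts in forebrain, at least 3709-fold higher. TCF21, a factor of visceral mesenchyme, stood at 166 ± 21.8 CPM, at least 1444-fold higher, and the homeobox gene MEIS1 was 12.7-fold higher at 358 ± 18.6 CPM (SD, n = 2). For the foregut and stomach mesenchyme factors, 5 of 12 tested members were higher and 2 lower (5 and 2 adjusted over the list alone). Higher members were PITX1, TCF21, OSR1, MEIS1 and HLX. Lower members were MEIS2 and NR2F1, but not without either Forebrain library or either Rumen library. The number of lower members was 0 without either Forebrain library or either Rumen library. The camera call for this list was adjusted p = 0.0265 (adjusted p = 0.293 with an estimated correlation). Of the enteric nervous system list, 7 of 16 tested members were higher and 3 lower (7 and 3 adjusted over the list alone). Lower members included ELAVL4 and S100B. Its members lay in both directions. PHOX2A, a factor of autonomic neurons, stood at 61.3 ± 1.83 CPM in rumen without counts in forebrain, whereas ELAVL4, a neuronal RNA-binding protein, was 4.99-fold lower in rumen, at 66.4 ± 11.3 against 331 ± 18.2 CPM (SD, n = 2). Among hedgehog, BMP and WNT signalling genes, 11 of 25 tested members were higher and 2 lower (13 and 2 adjusted over the list alone). Lower members were DKK3 and LEF1. Here the number of higher members was 6 without either Forebrain library or Rumen 1, and that of lower members 5 without either Liver library. The ligand BMP4 was 34.8-fold higher in rumen at 62.9 ± 1.86 CPM, and the secreted WNT modulator SFRP2 16.6-fold higher at 348 ± 56.6 CPM (SD, n = 2). The WNT effector LEF1 was 16.5-fold lower in rumen, at 9.90 ± 1.45 against 163 ± 33.7 CPM (SD, n = 2). In retinoic acid and FGF signalling, 6 of 14 tested members were higher and 3 lower (9 and 3 adjusted over the list alone), the number of lower members being 0 without either Forebrain library or either Rumen library. Lower members were CRABP1, STRA6 and FGF9, but not without either Forebrain library or either Rumen library. ALDH1A1, an enzyme of retinoic acid synthesis, was 35.1-fold higher in rumen at 87.5 ± 14.6 CPM, and the mesenchymal growth factor FGF7 80.3-fold higher at 43.7 ± 10.6 CPM (SD, n = 2). The camera call for retinoic acid and FGF signalling was adjusted p = 0.0265 (adjusted p = 0.293 with an estimated correlation).

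Forebrain stood above rumen in genes of neurons and glia. SLC17A6, the vesicular glutamate transporter of excitatory neurons, stood at 468 ± 52.5 CPM (SD, n = 2) in forebrain and had no counts in rumen, at least 4019.55-fold lower there. GAD1, which makes the inhibitory transmitter GABA, stood at 367 ± 22.3 CPM in forebrain and was at least 3158-fold lower in rumen (SD, n = 2). The neuronal tubulin TUBB3 was 17.3-fold lower in rumen, at 120.4 ± 5.11 against 2088 ± 158 CPM, and the microtubule protein MAP2 71.0-fold lower, at 35.2 ± 0.277 against 2505 ± 172 CPM (SD, n = 2). Among neuronal genes, 0 of 15 tested members were higher and 13 lower (0 and 14 adjusted over the list alone), and camera gave adjusted p = 1.76e-10 (adjusted p = 0.148 with an estimated correlation). FABP7, a fatty acid-binding protein of radial glia, was 25.0-fold lower in rumen, the glutamate transporter SLC1A3 24.1-fold lower and the Notch target HES5 25.2-fold lower. For radial glia and astrocytes, 1 of 11 tested members was higher and 8 lower (1 and 8 adjusted over the list alone). Only NES was higher, but not without either Forebrain library or either Rumen library. The number of higher members there was 0 without either Forebrain library or either Rumen library, and the camera call was adjusted p = 8.57e-05 (adjusted p = 0.293 with an estimated correlation). The neural stem cell factor SOX2, also a factor of foregut epithelium, did not pass the test in this comparison, at 92.1 ± 3.37 CPM in rumen and 82.1 ± 11.4 CPM in forebrain (SD, n = 2). OTX2, a head organizer gene, stood at 142 ± 56.9 CPM in forebrain without counts in rumen, and EMX2, a cortical homeobox gene, was 24.7-fold lower in rumen at 1.98 ± 0.629 against 49.0 ± 4.48 CPM (SD, n = 2). In the list of forebrain patterning factors, 0 of 10 tested members were higher and 5 lower (0 and 5 adjusted over the list alone), with a camera call of adjusted p = 0.00662 (adjusted p = 0.350 with an estimated correlation). Lower members were EMX2, LHX2, SIX3, OTX2 and POU3F2, but SIX3 did not pass without Forebrain 2 or either Rumen library. Of the oligodendrocyte lineage list, 1 of 9 tested members was higher and 5 lower (2 and 6 adjusted over the list alone). Only CSPG4 was higher, but not without either Forebrain library or either Rumen library. Lower members included OLIG1, MBP, NKX2-2 and BCAS1, but MBP did not pass without either Rumen library and NKX2-2 did not pass without Forebrain 2 or either Rumen library. OLIG1 stood at 179 ± 33.3 CPM in forebrain without counts in rumen (SD, n = 2). The number of lower oligodendrocyte lineage members was 3 without either Rumen library, and that of higher members 0 without either Forebrain library or either Rumen library and 2 without either Liver library. Of the respiratory genes, included as a check for neighbouring tissue, 0 of 5 tested members were higher and 5 lower (0 and 5 adjusted over the list alone), a count that was 1 without either Rumen library and 2 without either Forebrain library. Lower members were NKX2-1, SFTPC, SFTPA1, FOXJ1 and ABCA3, but NKX2-1 did not pass without Forebrain 2 or either Rumen library, SFTPA1 and FOXJ1 did not pass without either Forebrain library or either Rumen library and ABCA3 did not pass without Forebrain 1 or either Rumen library. Camera called that list lower in rumen at adjusted p = 0.0265 (adjusted p = 0.307 with an estimated correlation). The lung surfactant gene SFTPC stood at 10.5 CPM in Forebrain 1, 13.5 CPM in Forebrain 2 and 0.153 ± 0.216 CPM in rumen (SD, n = 2).

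Lists of rumen function, growth and chromatin gave mixed directions. AQP3, a water and glycerol channel, stood at 95.5 ± 19.7 CPM in rumen and 0.0768 ± 0.00647 CPM in forebrain, and ATP6V1B1, a proton pump subunit, at 88.2 ± 12.7 CPM in rumen without counts in forebrain (SD, n = 2). In the list of fatty acid, ion and urea transport, 5 of 18 tested members were higher and 3 lower (5 and 3 adjusted over the list alone). Higher members were SLC16A3, SLC9A3, SLC4A2, AQP3 and ATP6V1B1, but SLC16A3 and SLC4A2 did not pass without either Forebrain library or either Rumen library. Lower members were CA2, CA3 and CA4, but CA2 did not pass without Forebrain 2 or either Rumen library and CA4 did not pass without Forebrain 1 or Rumen 2. The higher members numbered 3 without either Forebrain library or either Rumen library and 8 without either Liver library, and the lower members 1 without Rumen 2 and 5 without either Liver library. Replication and mitosis genes stood above forebrain, among them the helicase subunit MCM3, 11.1-fold higher at 124 ± 6.64 CPM, and the ubiquitin-conjugating enzyme UBE2C, 9.50-fold higher at 73.7 ± 10.7 CPM (SD, n = 2). Of the proliferation list, 15 of 20 tested members were higher and 0 lower (15 and 0 adjusted over the list alone), at adjusted p = 2.61e-07 (adjusted p = 0.293 with an estimated correlation) by camera. In the immediate early and stress response list, 10 of 18 tested members were higher and 1 lower (10 and 1 adjusted over the list alone), and the higher members numbered 4 without either Forebrain library and 5 without Rumen 1. Only HSPH1 was lower. That list was called at adjusted p = 0.00259 (adjusted p = 0.297 with an estimated correlation). The transcription factor KLF4 was 10.5-fold higher in rumen at 48.4 ± 13.0 CPM (SD, n = 2). The heat shock gene HSPA1A, which has a near-identical copy, was 16.2-fold higher at 4206 ± 509 CPM (SD, n = 2), and its partner HSPH1 was 7.03-fold lower at 83.2 ± 13.3 CPM. Hypoxia and glycolysis genes went both ways. Of that list, 8 of 18 tested members were higher and 3 lower (8 and 3 adjusted over the list alone). Lower members were HK1, PFKP and ALDOC, but HK1 and PFKP did not pass without either Forebrain library or either Rumen library. The higher members numbered 3 without either Forebrain library or either Rumen library, and the lower members 1 without either Forebrain library or either Rumen library. NDRG1 was 5.97-fold higher in rumen, and the brain aldolase ALDOC 17.6-fold lower. Of the imprinted genes, which are expressed from 1 parental allele, 7 of 21 tested members were higher and 7 lower (8 and 8 adjusted over the list alone). IGF2 was 311-fold higher in rumen, at 9169 ± 1008 against 29.3 ± 32.7 CPM, a log2 fold change of 8.28 that was 7.47 without Forebrain 1 and 10.56 without Forebrain 2. H19 was 241-fold higher, at 8989 ± 564 against 37.2 ± 24.6 CPM, a log2 fold change of 7.91 that was 8.86 without Forebrain 2 (SD, n = 2). NNAT was 56.5-fold lower in rumen, at 92.2 ± 10.4 against 5214 ± 502 CPM, and DIRAS3 14.3-fold lower, at 89.4 ± 12.3 against 1281 ± 407 CPM (SD, n = 2). Of the Polycomb and Trithorax list, 5 of 21 tested members were higher and 3 lower (0 and 0 adjusted over the list alone). Higher members were EZH2, RING1, CBX2, CBX8 and MEN1, but EZH2, RING1, CBX8 and MEN1 did not pass without either Forebrain library or either Rumen library and CBX2 did not pass without either Forebrain library or Rumen 2. Lower members were BMI1, RNF2 and DPY30, but not without either Forebrain library or either Rumen library. Its higher members numbered 0 without either Forebrain library or Rumen 2, 1 without Rumen 1 and 11 without either Liver library, and its lower members 0 without either Forebrain library or either Rumen library. Endothelial genes were higher for 5 of 13 members and lower for 0 (5 and 0 adjusted over the list alone), the higher number being 0 without either Forebrain library or Rumen 1, 2 without Rumen 2 and 8 without either Liver library. Higher members were KDR, TEK, VWF, ERG and EMCN, but KDR and VWF did not pass without either Forebrain library or Rumen 1 and TEK, ERG and EMCN did not pass without either Forebrain library or either Rumen library. For mesothelium, 3 of 6 tested members were higher and 1 lower (5 and 1 adjusted over the list alone), the higher number being 5 without either Liver library. Higher members were UPK1B, KRT19 and KRT7, but UPK1B did not pass without Forebrain 1 or Rumen 1. Only GPM6A was lower. The neuronal membrane protein GPM6A, listed there as a mesothelial marker, was 593-fold lower in rumen, at 2.05 ± 0.0263 against 1221 ± 185 CPM (SD, n = 2).

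Across all 11478 tested genes, 2329 were higher and 2473 lower in rumen than in forebrain, 41.8% of those tested, with 1342 and 1361 at 4-fold or more. Camera called 13 of 37 lists with the preset correlation, 9 of them higher in rumen. With an estimated correlation, camera called 0 lists in each of the 3 comparisons. That version rests on 3 residual degrees of freedom and decides little. Neurons had an estimated correlation of 0.0040, under the preset 0.01, and still were not called (camera adjusted p = 0.148). For stratified squamous epithelium and extracellular matrix the estimates were 0.373 and 0.367. The adjusted p with the preset correlation may be far too small for such lists. The median, mean and test differed in sign for hepatocyte secreted proteins, macrophages, pancreas and spleen neighbours, skeletal muscle and germline genes. The counts changed when a library was left out, to similar values for either library of a tissue. Without Forebrain 1 they were 1001 higher and 1223 lower, without Forebrain 2 1040 and 1226, without Rumen 1 1256 and 1171, without Rumen 2 1320 and 1119, without Liver 1 3621 and 3830, and without Liver 2 3620 and 3843. With only the 4 rumen and forebrain libraries they were 3681 and 3734, and against a 2-fold change with edgeR's glmTreat 1302 and 1379.

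**Figure D1:**
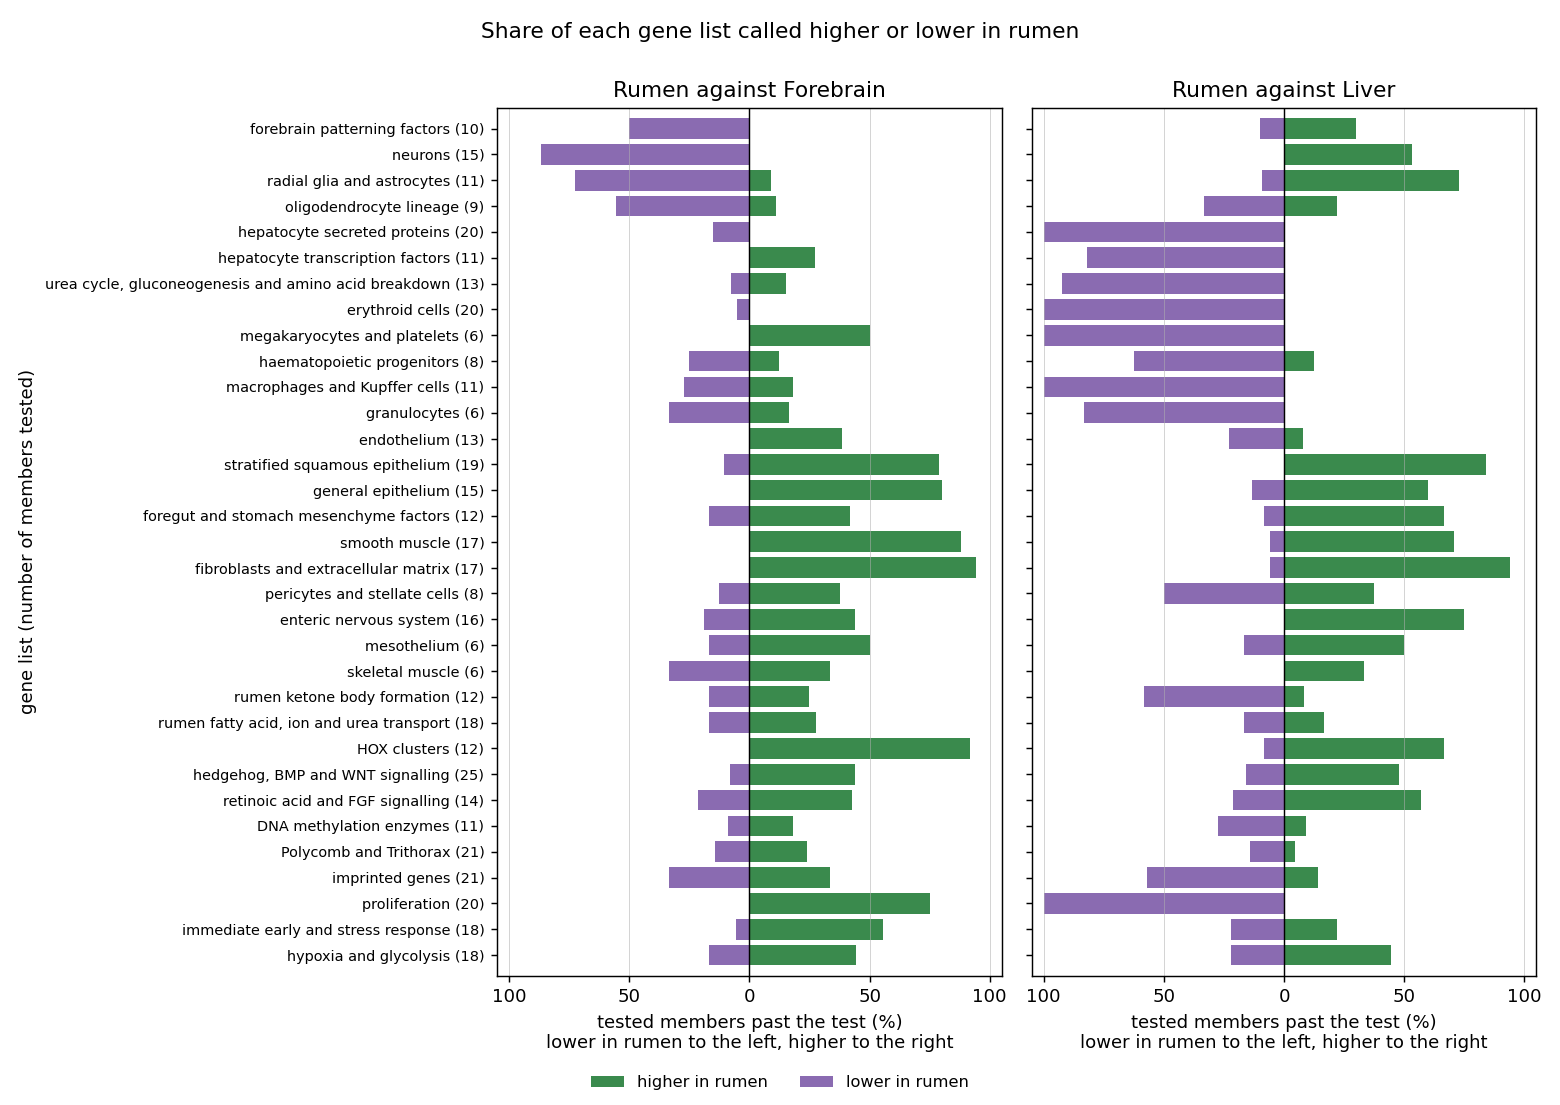
Share of the tested members of each gene list that passed the test, for rumen against forebrain (left) and rumen against liver (right), in percent of tested members, with lower in rumen drawn to the left of 0 and higher to the right, for the 33 lists with at least 6 tested members (numbers in brackets). Neurons reached 13 of 15 lower against forebrain, and erythroid cells and hepatocyte secreted proteins 20 of 20 lower against liver.

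Rumen and liver, organs with epithelia of foregut endoderm, were compared next under the same question. Liver exceeded rumen in plasma proteins, in enzymes of amino acid breakdown and in blood-forming cells, and rumen exceeded liver in epithelial, muscle, matrix and nerve genes. The apolipoprotein APOA2 stood at 8193 ± 821 CPM (SD, n = 2) in liver and had no counts in rumen, where the floor lay at least 71034.8-fold below its pooled level in liver. Transferrin, TF, stood at 9008 ± 4145 CPM and the fibrinogen chain FGG at 1876 ± 90.4 CPM in liver (SD, n = 2), at least 75833.9-fold and 16138-fold lower in rumen. HPD, an enzyme of tyrosine breakdown, stood at 394 ± 47.9 CPM in liver without counts in rumen, and the urea cycle enzyme ASS1 was 5.48-fold lower in rumen, at 48.0 ± 1.14 against 263 ± 85.4 CPM (SD, n = 2; adjusted p = 0.00108, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among hepatocyte secreted proteins, 0 of 20 tested members were higher and 20 lower (0 and 20 adjusted over the list alone), and the camera call was adjusted p = 4.35e-22 (adjusted p = 0.0743 with an estimated correlation). Of the urea cycle, gluconeogenesis and amino acid breakdown list, 0 of 13 tested members were higher and 12 lower (0 and 12 adjusted over the list alone), at adjusted p = 1.66e-08 (adjusted p = 0.109 with an estimated correlation). Among hepatocyte transcription factors, 0 of 11 tested members were higher and 9 lower (0 and 9 adjusted over the list alone). The lower number there was 4 without Rumen 1, and camera gave adjusted p = 0.000964 (adjusted p = 0.151 with an estimated correlation).

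Blood cell genes were abundant in liver, the main site of fetal blood formation. ALAS2, the erythroid enzyme of haem synthesis, was 492-fold lower in rumen, at 6.10 ± 0.353 against 3006 ± 841 CPM (SD, n = 2; log2 fold change -8.94 ± 0.38 (SE); adjusted p = 3.48e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the erythroid list, 0 of 20 tested members were higher and 20 lower (0 and 20 adjusted over the list alone), at adjusted p = 2.89e-16 (adjusted p = 0.151 with an estimated correlation). The platelet chemokine PF4 was 171-fold lower in rumen, at 4.79 ± 0.0429 against 822 ± 375 CPM (SD, n = 2). In the list of megakaryocytes and platelets, 0 of 6 tested members were higher and 6 lower (0 and 6 adjusted over the list alone), at adjusted p = 0.000111 (adjusted p = 0.151 with an estimated correlation). For haematopoietic progenitors, 1 of 8 tested members was higher and 5 lower (1 and 5 adjusted over the list alone), with the higher number being 0 without Rumen 2. Only KIT was higher, but not without Rumen 2. Lower members were CD34, MYB, SPI1, GATA2 and LMO2. The progenitor factor MYB was 13.5-fold lower in rumen and the surface protein CD34 3.29-fold lower. Camera called the progenitor list at adjusted p = 0.0202 (adjusted p = 0.305 with an estimated correlation). CD68, a lysosomal protein of macrophages, was 32.8-fold lower in rumen, at 1.27 ± 0.474 against 42.2 ± 13.5 CPM (SD, n = 2). For macrophages and Kupffer cells, 0 of 11 tested members were higher and 11 lower (0 and 11 adjusted over the list alone), at adjusted p = 8.63e-06 (adjusted p = 0.291 with an estimated correlation). The lower number was 6 without Rumen 1 and 7 without Rumen 2. Granulocyte genes were higher for 0 and lower for 5 of 6 members (0 and 5 adjusted over the list alone), the lower number being 3 without either Rumen library, at adjusted p = 0.00490 (adjusted p = 0.415 with an estimated correlation). Lower members were MPO, ELANE, S100A8, LTF and CAMP, but ELANE did not pass without either Forebrain library or either Rumen library and CAMP did not pass without either Rumen library. Of the lymphocyte list, 2 members could be tested, with 0 higher and 1 lower. The T cell marker CD8A was lower in rumen, at 0.115 ± 0.162 against 1.47 ± 0.188 CPM (SD, n = 2). It was the only lower gene of the list, and the lower number was 0 without either Forebrain library or Rumen 2 and 5 without Liver 2, where the filter, run again without that library, kept 9 members. Adjusted over the list alone, 1 lymphocyte gene was higher and 1 lower.

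Proliferation genes, higher in rumen than in forebrain, were lower in rumen than in liver. The mitotic gene CENPF was 11.1-fold lower in rumen, at 53.4 ± 1.72 against 590.4 ± 37.2 CPM, and RRM2, a subunit of ribonucleotide reductase, 6.70-fold lower (SD, n = 2). Of this list, 0 of 20 tested members were higher and 20 lower (0 and 20 adjusted over the list alone), at adjusted p = 1.90e-08 (adjusted p = 0.151 with an estimated correlation). The lower number was 11 without Rumen 2 and 13 without Rumen 1. The maintenance DNA methyltransferase DNMT1 was 5.62-fold lower in rumen, at 27.4 ± 0.489 against 154 ± 5.30 CPM, while the de novo methyltransferase DNMT3A was 3.17-fold higher, at 169 ± 17.9 against 53.1 ± 2.07 CPM (SD, n = 2). Of the DNA methylation enzymes, 1 of 11 tested members was higher and 3 lower (1 and 3 adjusted over the list alone), the lower number being 1 without either Rumen library and 6 without either Liver library. Only DNMT3A was higher. Lower members were DNMT1, DNMT3B and UHRF1, but DNMT3B and UHRF1 did not pass without either Rumen library. The mitochondrial thiolase ACAT1 was 3.73-fold lower and the acetyl-CoA synthetase ACSS1 16.6-fold lower in rumen. For rumen ketone body formation, 1 of 12 tested members was higher and 7 lower (1 and 7 adjusted over the list alone), at adjusted p = 0.00722 (adjusted p = 0.191 with an estimated correlation). Only BDH2 was higher, but not without either Forebrain library or either Rumen library. The higher number was 0 without either Forebrain library or either Rumen library. Of the imprinted genes, 3 of 21 tested members were higher and 12 lower (3 and 12 adjusted over the list alone), at adjusted p = 0.0482 (adjusted p = 0.421 with an estimated correlation). Higher members were MEST, NDN and DIRAS3, but NDN did not pass without either Rumen library. The higher number was 6 without Liver 2, and the lower number 6 without Rumen 1 and 7 without Rumen 2. NNAT was 57.4-fold lower in rumen, at 92.2 ± 10.4 against 5295 ± 2484 CPM, whereas IGF2 at 9169 ± 1008 and 7265 ± 823 CPM and H19 at 8989 ± 564 and 11851 ± 5271 CPM did not pass (SD, n = 2).

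Above liver, the rumen again had the genes of a squamous epithelium with a muscle and nerve layer. TRIM29, a gene of basal squamous cells, stood at 195 ± 32.9 CPM (SD, n = 2) in rumen without counts in liver, at least 1883.58-fold higher. The serine protease ST14 was 22.4-fold higher at 75.5 ± 21.3 CPM. The contractile genes CNN1 and ACTG2 were 648-fold and 739-fold higher, at 613 ± 57.5 and 1475 ± 103 CPM (SD, n = 2). The collagens COL12A1 and COL1A2 were 59.6-fold and 35.9-fold higher. VIP, a transmitter of enteric neurons, stood at 47.3 ± 11.4 CPM in rumen, the enteric glial factor SOX10 at 21.2 ± 2.00 CPM and SOX2 at 92.1 ± 3.37 CPM, all without counts in liver (SD, n = 2). Stratified squamous epithelium had 16 of 19 tested members higher and 0 lower (16 and 0 adjusted over the list alone), at adjusted p = 4.70e-09 (adjusted p = 0.151 with an estimated correlation). Of the smooth muscle genes, 12 of 17 tested members were higher and 1 lower (12 and 1 adjusted over the list alone), at adjusted p = 3.07e-07 (adjusted p = 0.151 with an estimated correlation), the lower number being 2 without Liver 2. Only HHIP was lower. Fibroblasts and extracellular matrix had 16 of 17 tested members higher and 1 lower (16 and 1 adjusted over the list alone), at adjusted p = 4.03e-09 (adjusted p = 0.151 with an estimated correlation). Only PDGFRB was lower. For the enteric nervous system, 12 of 16 tested members were higher and 0 lower (13 and 0 adjusted over the list alone), at adjusted p = 6.97e-08 (adjusted p = 0.109 with an estimated correlation), and the lower number was 1 without Liver 2. Among foregut and stomach mesenchyme factors, 8 of 12 tested members were higher and 1 lower (9 and 1 adjusted over the list alone), at adjusted p = 0.000989 (adjusted p = 0.151 with an estimated correlation). Only GATA4 was lower. In the HOX clusters, 8 of 12 tested members were higher and 1 lower (8 and 1 adjusted over the list alone), at adjusted p = 0.00199 (adjusted p = 0.151 with an estimated correlation), and the higher number was 4 without Rumen 1 and 5 without Rumen 2, the lower number 0 without Rumen 2. Only HOXA9 was lower, but not without Rumen 2. HOXB3 was 8.95-fold higher in rumen at 65.8 ± 1.93 CPM, and HOXC5 stood at 10.7 ± 1.41 CPM without counts in liver (SD, n = 2). Of the pericyte and stellate cell list, 3 of 8 tested members were higher and 4 lower (3 and 4 adjusted over the list alone), the higher number being 1 without either Rumen library. Higher members were KCNJ8, CSPG4 and DES, but KCNJ8 and CSPG4 did not pass without either Rumen library. Lower members were LRAT, RELN, HGF and PDGFRB, but LRAT did not pass without either Rumen library. RELN, a matrix protein of hepatic stellate cells and of early cortical neurons, was 15.4-fold lower in rumen, at 7.997 ± 0.381 against 123 ± 9.99 CPM (SD, n = 2).

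Lists for tissues near the rumen or unlikely in it gave few tested genes. Of the skeletal muscle genes, 2 of 6 tested members were higher and 0 lower (2 and 0 adjusted over the list alone), the higher number being 0 without either Rumen library and 1 without either Forebrain library and the lower number 1 without Liver 1. Those 2 were the troponin TNNT3, at 37.9 ± 0.525 against 9.17 ± 6.12 CPM, and the creatine kinase CKM, at 0.928 ± 0.0129 CPM without counts in liver (SD, n = 2). For pancreas and spleen neighbours, 2 of 3 tested members were higher and 0 lower (2 and 0 adjusted over the list alone), the higher number being 1 without either Forebrain library or Rumen 2. They were somatostatin (SST), also made by neurons, at 8.74 ± 0.449 against 0.161 ± 0.227 CPM, and the elastase CELA1, at 3.23 ± 2.94 against 0.149 ± 0.211 CPM (SD, n = 2). In glandular stomach and intestine, 1 of 3 tested members was higher and 2 lower (1 and 2 adjusted over the list alone). Its higher number was 0 without either Forebrain library or either Rumen library, and its lower number 1 without either Rumen library. ANXA10, a gene of gastric epithelium, stood at 1.55 ± 0.677 CPM in rumen without counts in liver, VIL1, a brush border protein, at 1.12 ± 0.289 against 26.3 ± 13.9 CPM and HNF4G, a factor of intestine and liver that was lower in rumen, at 1.23 ± 0.529 CPM there (SD, n = 2). Among germline genes, 1 of 3 tested members was higher and 0 lower (1 and 0 adjusted over the list alone), the higher number being 0 without either Rumen library and the lower number 1 without Liver 1. It was the meiotic gene SYCP3, at 38.1 ± 1.02 against 16.8 ± 2.88 CPM (SD, n = 2).

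Between rumen and liver, 2434 genes were higher and 2507 lower in rumen, 43.0% of those tested. Camera called 22 of 37 lists with the preset correlation, 11 of them higher in rumen. The median, mean and test differed in sign for glandular stomach and intestine and for immediate early and stress response. Without Rumen 1 the counts were 1333 and 1143, without Rumen 2 1402 and 1105, and the lower count was 3792 without Liver 2, all over 1.5 times from the values above. Against a 2-fold change with edgeR's glmTreat they were 1369 and 1418, and upper quartile scaling moved the median log2 fold change of all genes by 0.15, with 55.4% of calls higher instead of 49.3%.

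Liver and forebrain, the pair of reference tissues, were compared to show what the rumen was measured against. Liver held plasma protein, blood cell and cell cycle genes, and forebrain neural genes. AHSG stood at 83178 ± 22271 CPM (SD, n = 2) in liver, SERPINA1 at 54312 ± 16131 CPM and AFP at 24399.7 ± 4299 CPM, all without counts in forebrain. ALB was 2434-fold higher in liver, at 31206 ± 14148 against 12.9 ± 3.68 CPM (SD, n = 2; adjusted p = 3.86e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ALAS2 was 447-fold higher, CD68 28.8-fold and the haem oxygenase HMOX1, which breaks down haem, 81.6-fold, at 242 ± 6.91 CPM (SD, n = 2). CENPF was 40.1-fold higher in liver, MCM3 27.7-fold and UBE2C 32.5-fold. DNMT1 was 7.78-fold higher and its cofactor UHRF1 18.4-fold. Against these, TUBB3 stood at 2088 ± 158 CPM in forebrain and the neurofilament NEFL at 198 ± 46.9 CPM, both without counts in liver (SD, n = 2). FABP7 was 275-fold and the WNT inhibitor family member DKK3 176-fold lower in liver. HOXA5 and HOXA9 stood at 27.2 ± 9.11 and 9.74 ± 3.67 CPM in liver and had no counts in forebrain (SD, n = 2).

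The list counts followed the same division. Hepatocyte secreted proteins had 20 of 20 tested members higher and 0 lower (20 and 0 adjusted over the list alone), at adjusted p = 7.89e-16 (adjusted p = 0.121 with an estimated correlation). Erythroid cells had 20 of 20 tested members higher and 0 lower (20 and 0 adjusted over the list alone), at adjusted p = 2.00e-11 (adjusted p = 0.194 with an estimated correlation). Of the proliferation genes, 20 of 20 tested members were higher and 0 lower (20 and 0 adjusted over the list alone), at adjusted p = 2.16e-10 (adjusted p = 0.194 with an estimated correlation). Neurons had 0 of 15 tested members higher and 15 lower (0 and 15 adjusted over the list alone), at adjusted p = 2.85e-10 (adjusted p = 0.121 with an estimated correlation). Radial glia and astrocytes had 1 of 11 tested members higher and 10 lower (1 and 10 adjusted over the list alone), at adjusted p = 1.60e-05 (adjusted p = 0.194 with an estimated correlation). The single higher member, ALDH1L1, which is expressed in hepatocytes as well as astrocytes, stood at 272 ± 240.0 CPM in liver and 2.36 ± 0.577 CPM in forebrain (SD, n = 2) and was named after its values were seen. Within the HOX clusters, 8 of 12 tested members were higher and 0 lower (8 and 0 adjusted over the list alone), at adjusted p = 0.00296 (adjusted p = 0.194 with an estimated correlation). Of all tested genes, 3499 were higher and 3133 lower in liver, 57.8%, and camera called 17 lists with the preset correlation. The median, mean and test differed in sign for stratified squamous epithelium, foregut and stomach mesenchyme factors and mesothelium. Without Forebrain 1 the higher count was 2001, without Forebrain 2 the counts were 1953 and 2035, and the lower count against a 2-fold change with glmTreat was 2079.

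Tissue-enriched genes were those higher by at least 4-fold than in both other tissues and past the test in both comparisons. Rumen-enriched thus means above forebrain and liver only, and such genes may be as high in tissues that were not sequenced here. Rumen had 489 of them, forebrain 1041 and liver 1114. The leading genes named below follow the naming rule, with its minimum mean CPM and with provisional LOC names and ENSBTAG identifiers passed over. In rumen this passed over LOC507527, at a mean of 21.4 CPM, which ranked between ZNF750 and ITLN2. After PITX1 and IVL, the leading rumen genes were the uroplakin-like UPK3BL1 at 284 ± 43.6 CPM, PHOX2A at 61.3 ± 1.83 CPM, the gasdermin GSDMC at 165 ± 9.08 CPM, KRT15, the epidermal differentiation factor ZNF750 at 21.5 ± 3.53 CPM, the lectin ITLN2 at 21.4 ± 0.297 CPM, KRT4 and the keratinocyte gene KRTDAP at 376 ± 61.9 CPM (SD, n = 2). Those of forebrain, after SLC17A6, GAD1, OLIG1 and OTX2, were the glutamate transporter SLC1A6 at 117 ± 3.49 CPM, VXN at 102 ± 9.90 CPM, the receptor GPR12 at 86.1 ± 17.9 CPM, the transcription factor TFAP2B at 52.1 ± 14.9 CPM, MGC148318 at 48.2 ± 16.0 CPM and C2H2orf80 at 47.2 ± 1.54 CPM (SD, n = 2). Liver was led by the fetuin FETUB at 8502 ± 3609.7 CPM, APOA2, the inhibitor heavy chain ITIH3 at 3544 ± 3101 CPM, FGG, the secreted phosphoprotein SPP2 at 1388 ± 555 CPM, SERPINA1, the kininogen KNG1 at 1127 ± 268 CPM, AFP, the plasma glycoprotein A1BG at 793 ± 30.2 CPM and the anion transporter SLC22A7 at 621 ± 522 CPM (SD, n = 2). Of the rumen-enriched genes, 31 had no counts in the other 4 libraries, against 108 of the forebrain-enriched and 112 of the liver-enriched genes.

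Fisher's exact test, one-sided and adjusted over the lists of each tissue, set the enriched genes against the lists. The rumen-enriched genes held 15 of 17 extracellular matrix genes (adjusted p = 1.04e-17, Fisher's exact test), 15 of 19 of stratified squamous epithelium (adjusted p = 1.38e-16), 11 of 17 of smooth muscle (adjusted p = 9.10e-11), 7 of 15 of general epithelium (adjusted p = 1.08e-05) and 6 of 12 of the HOX clusters (adjusted p = 3.19e-05). They also held 6 of 25 of hedgehog, BMP and WNT signalling (adjusted p = 0.00317, Fisher's exact test), 4 of 12 foregut and stomach mesenchyme factors, 3 of 6 of mesothelium (adjusted p = 0.00646 each) and 4 of 16 of the enteric nervous system (adjusted p = 0.0162). The forebrain-enriched genes held 13 of 15 neuronal genes (adjusted p = 8.57e-11, Fisher's exact test) and 8 of 11 of radial glia and astrocytes (adjusted p = 1.06e-05). The liver-enriched genes held 20 of 20 each of hepatocyte secreted proteins and erythroid cells (adjusted p = 8.71e-20, Fisher's exact test), 11 of 13 of the urea cycle list (adjusted p = 5.51e-09), 11 of 20 of proliferation (adjusted p = 4.67e-06), 8 of 11 each of hepatocyte transcription factors and macrophages, 6 of 6 of megakaryocytes and platelets (adjusted p = 5.13e-06 each) and 4 of 6 of granulocytes (adjusted p = 0.00522). Fisher's exact test takes the genes of a list as independent. By camera no list was called with an estimated correlation, a version that rests on 3 residual degrees of freedom and decides little here. With the preset correlation, camera did not call mesothelium in rumen against forebrain, adjusted p = 0.161 (adjusted p = 0.427 with an estimated correlation), or against liver, adjusted p = 0.240 (adjusted p = 0.421 with an estimated correlation), and its enriched members included KRT19, a member of the general epithelium list too. Nor did it call the enteric nervous system, adjusted p = 0.110 (adjusted p = 0.327 with an estimated correlation), or hedgehog, BMP and WNT signalling, adjusted p = 0.0520 (adjusted p = 0.297 with an estimated correlation), in rumen against forebrain, or granulocytes, adjusted p = 0.112 (adjusted p = 0.608 with an estimated correlation), in liver against forebrain. The 2 comparisons behind each count share libraries. Independent lists of the same sizes would overlap by 156 genes for rumen, 217 for forebrain and 287 for liver, and 20 simulated sets of unchanged tissues gave a median of 0 and at most 1 for rumen, 0 for forebrain and 0 for liver. Hardly any gene passes in such sets, so they give no baseline for lists of these sizes, and part of the overlap above that of independent lists may come from the shared libraries. With glmTreat against a 4-fold change the counts were 241 for rumen, 543 for forebrain and 541 for liver.

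**Figure D2:**
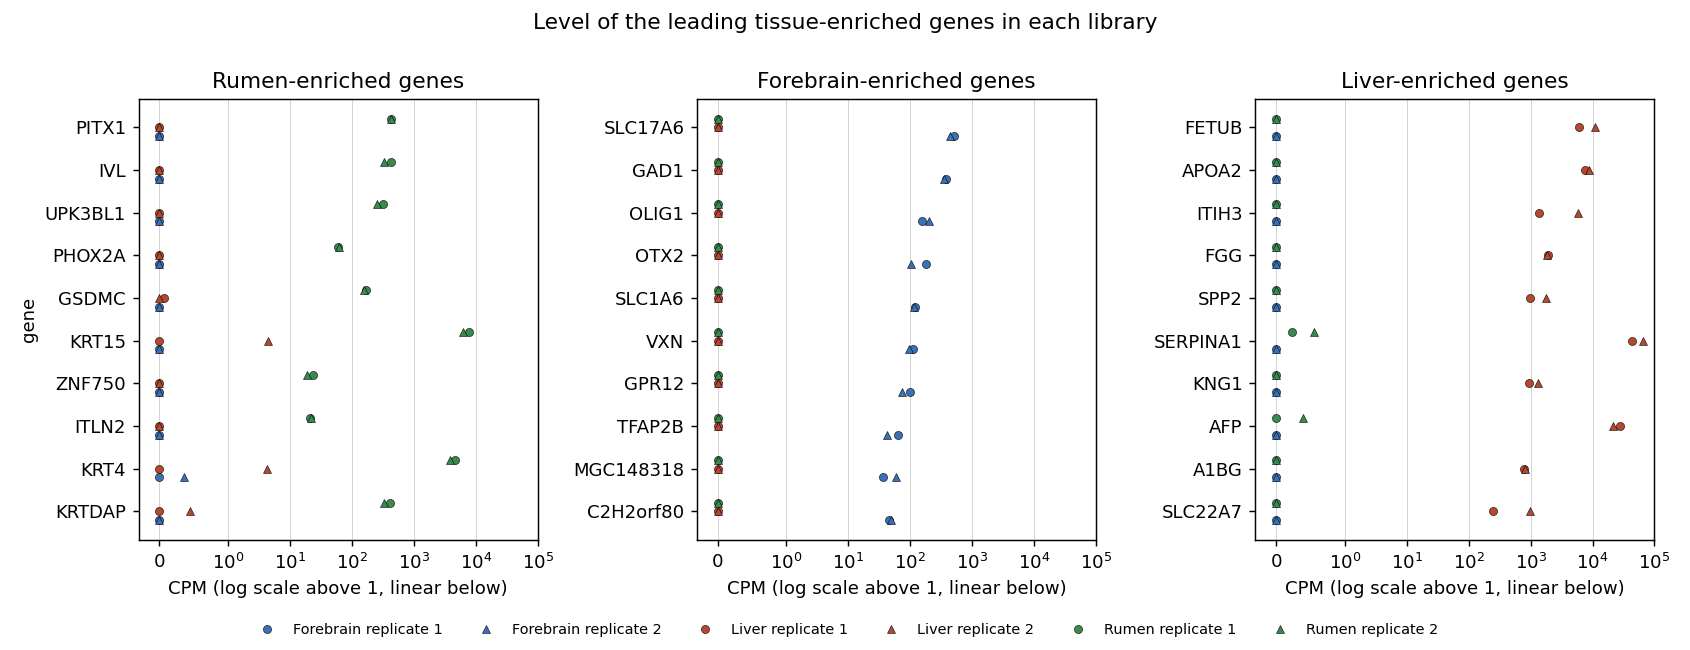
Level in each of the 6 libraries, in CPM on an axis that is logarithmic above 1 and linear below, of the 10 tissue-enriched genes per tissue with the largest smaller fold change. Only genes with a mean of at least 20 CPM in that tissue and no provisional LOC name or ENSBTAG identifier were ranked. Circles are replicate 1 and triangles replicate 2, coloured by tissue. The rumen points of KRT15 have a mean of 7067 ± 1125 CPM and the liver points of SERPINA1 a mean of 54312 ± 16131 CPM (SD, n = 2), and the genes sit far lower in the other tissues. KRT15 and KRT4 were not at 0 in liver, with log2 fold changes of 11.6 and 10.9 of rumen over liver.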

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

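The alternatives were chosen before the data were examined, and the genes named outside the rule were chosen after their values were seen. No call changed direction under any of them. Of 621 calls of named genes, 9687 values under the alternatives stayed past the threshold and 833 did not, most of them with a library left out. Of the medians of lists, 1541 stayed within their spread and 346 moved further. Of the 9 counts of genes, 123 values lay within 1.5 times the reported count and 36 did not. The other scalings, both filters, DESeq2's and voom's tests and the legacy dispersion kept every count within 1.5 times.

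Against a 2-fold change with glmTreat, which by construction asks for larger effects, 1302 genes were higher and 1379 lower in rumen than in forebrain, 1369 and 1418 in rumen than in liver, and 2079 lower in liver than in forebrain. Enriched genes against a 4-fold change numbered 241 for rumen, 543 for forebrain and 541 for liver. A minimum log2 fold change of 1 gave 845, 1667 and 1777, and one of 3 gave 305, 688 and 702. With only the rumen and forebrain libraries, 3681 genes were higher and 3734 lower. Leaving out 1 library at a time, where the lone library of a tissue is assumed to vary like the others, gave 1001 to 3621 higher and 1119 to 3843 lower in rumen than in forebrain, 1333 to 3481 and 1105 to 3792 in rumen than in liver, and 1953 to 4398 and 2035 to 3993 in liver than in forebrain. For enriched genes these ranges were 354 to 544 for rumen, 740 to 1126 for forebrain and 769 to 1377 for liver. Counts were lower without a forebrain or rumen library and higher without a liver library. For rumen against forebrain they were also higher with no liver library at all. The main fit shares 1 estimate of spread per gene over the 3 tissues. The log2 ratio of the liver pair had an SD of 0.945 over abundant genes, against 0.249 in forebrain and 0.211 in rumen. The spread of the liver pair thus entered the p-values of rumen against forebrain.

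The replicate block, with the replicate number as a factor, gave 2225 higher and 2338 lower in rumen than in forebrain, 2261 and 2356 in rumen than in liver, 3385 and 3030 in liver than in forebrain, and 489, 1036 and 1091 enriched genes for rumen, forebrain and liver. The labels do not say that a number marks a fetus, and libraries with the same number did not deviate together (correlation 0.0754 for forebrain and liver, -0.0585 for forebrain and rumen, -0.00177 for liver and rumen).

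With 2 libraries per tissue and 3 residual degrees of freedom, genes that did not pass are not shown to be equal. Changes of 2-fold were mostly missed in simulated data. Far fewer genes changed there than passed here, so how often such changes were missed here is not known. Genes near the floor of 3 counts cannot be given a fold.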

Other observations

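The tests of the erythroid share of liver and of haemoglobin outside liver were chosen only after the result was seen, as were the 8 gene families examined, of which 4 are described, and the other tests were written before. Ribosomal protein genes, which build the subunits of the cytosolic ribosome, took 27.8 ± 1.86% of counts in rumen, 13.7 ± 1.68% in forebrain and 6.94 ± 0.896% in liver (SD, n = 2). In rumen 69 of 80 were higher than in liver and 0 lower, from 37 to 72 higher with a library left out, at adjusted p = 5.23e-18 (adjusted p = 0.645 with an estimated correlation) by camera. Against forebrain 62 were higher and 0 lower, from 7 to 74 higher with a library left out, at adjusted p = 5.35e-12 (adjusted p = 0.488 with an estimated correlation). These genes have many processed copies, so their counts are uncertain. NADH dehydrogenase subunits, of the first complex of the respiratory chain, were lower in rumen than in forebrain for 21 of 35 and higher for 0, from 3 to 29 lower with a library left out, at adjusted p = 9.77e-05 (adjusted p = 0.488 with an estimated correlation). Liver was below forebrain too, for 22 with 0 higher (from 12 to 26 lower with a library left out), at adjusted p = 0.000283 (adjusted p = 0.519 with an estimated correlation), and against liver rumen had 7 higher and 4 lower (from 2 to 11 and from 1 to 10), not called at adjusted p = 0.613 (adjusted p = 0.886 with an estimated correlation). Complement genes were lower in rumen than in liver for 14 of 15 and higher for 1 (9 lower without Rumen 1 and 0 higher without either Rumen library), at adjusted p = 1.92e-07 (adjusted p = 0.109 with an estimated correlation). Genes of the CYP2, CYP3A and CYP4 groups of cytochrome P450, the only groups of that superfamily examined together, were higher in rumen than in forebrain for 10 of 14, from 6 to 11 with a library left out, at adjusted p = 0.000107 (adjusted p = 0.488 with an estimated correlation). Liver was above forebrain too, for 7 with 0 lower (from 3 to 9 higher with a library left out), at adjusted p = 0.00997 (adjusted p = 0.519 with an estimated correlation), and against liver rumen had 6 higher and 4 lower (from 4 to 7 and from 1 to 6), not called at adjusted p = 0.591 (adjusted p = 0.886 with an estimated correlation).

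The liver libraries differed from each other more than those of the other tissues. HBG stood at 109193 CPM in Liver 1 and 37478 in Liver 2, ALB at 41209.8 and 21201, and the transferrin receptor TFRC at 528 and 28.5. Counting noise is argued against by an SD of the log2 ratio of 0.945 over genes with a mean count of at least 1000. A first test of the erythroid share, whether erythroid genes move together, had 16 of 20 higher in Liver 1 and 4 lower. Their median log2 ratio of Liver 1 over Liver 2 was 0.779. It was replaced after this was seen by a test on 32 abundant hepatocyte genes, whose log2 ratios should then share a value. Instead these had an SD of 0.762 and a median of -0.254, against a different share of erythroid cells as the whole cause. Such a share as part of the cause stays open. A bias along chromosomes cannot be told apart, since the mean rank correlation of genes 5 to 20 places apart, 0.0168, lay above the largest of 200 shuffles, 0.00861, but under the 0.05 set beforehand, and was 0.0270 in the forebrain pair, and a difference between animals stays open and untested.

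In the forebrain pair, ventral genes were higher in Forebrain 2. NKX2-1, a factor of the ventral forebrain and also of lung and thyroid, stood at 3.90 CPM in Forebrain 1 and 68.7 in Forebrain 2, and DLX1, of inhibitory neuron precursors, at 2.36 and 19.6. Lung or thyroid tissue is argued against, though weakly, by a median log2 ratio of -0.286 over the 3 of 9 markers that could be tested. That median is the value of ABCA3. SFTPC was slightly higher in Forebrain 2, at a log2 ratio of 0.359. The thyroid gene TG had only 8 and 4 counts in Forebrain 1 and 2, so thyroid tissue was hardly tested. A larger share of ventral and basal forebrain in Forebrain 2 stays open and cannot be told apart from a difference between animals, with a median log2 ratio of 0.953, just under the 1 set beforehand, over 7 of 22 further markers (percentile 99.98 of 10000 random lists matched on expression). Among them the hypothalamic factor OTP stood at 11.5 and 32.2 CPM and SOX14, of thalamic neurons, at 32.5 and 21.4.

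Haemoglobin transcripts were present outside liver. HBG stood at 412 and 427 CPM in Forebrain 1 and 2 and at 458 and 385 CPM in Rumen 1 and 2. Reads of the liver libraries assigned to the others are argued against as the whole source, since AHSG sat at least 186-fold below the fraction of its liver level at which HBG sat. The gap was smaller for ALB in Forebrain 1 and 2, at 0.0495% and 0.0328% of its liver level, against 0.561% and 0.583% for HBG. SERPINA1 and AFP sat at 0% there. In Rumen 1 and 2 ALB sat at 0.00123% and 0.00325%. Blood in the tissues stays open and cannot be told apart from other sources, since HBG, HBA, HBM, AHSP and ALAS2 sat at 0.0645% of their liver level or more in each of the 4 libraries, against 0.05% set after the values were seen, while SLC4A1, of the red cell membrane, sat at 0.0104% and 0% in Forebrain 1 and 2 and at 0.00488% and 0% in Rumen 1 and 2. The erythroid factors GATA1 and KLF1 had no counts in 3 and 2 of these libraries, and the transcripts that circulating cells carry are not in the data.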
